A study of Homo sapiens with 12 samples.

How the data were processed

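Chromatin immunoprecipitation followed by sequencing was carried out in HEK293T cells, a human embryonic kidney line widely used for transfection, with antibodies against 5 proteins: INTS13, INTS11, HDGF, ZEB1 and ZNF609. There were 2 libraries per protein, and 2 further libraries of input chromatin. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures, so the spread between replicates, and any p-value that rests on it, may be technical. Input libraries were not used here, since the values analysed were lists of peaks.

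Per the submitters' processing notes, the reads were handled with FastQC, Trimmomatic, Bowtie, Picard and MACS2; tool versions, the control given to the peak caller, its thresholds and the genome build are not given in the sources used here. The deposited files were peak lists, 1 per replicate, so peaks had been called on each library by itself and not on pooled replicates. The fold of each peak is the authors' ratio of the summit height to the caller's background, on a linear scale. The p-value and q-value of each peak are the authors' values as deposited, on a -log10 scale, and the deposited score is a whole number equal to 10 times the -log10 q. These values belong to each peak in its own list, and were used only to rank, filter and describe peaks within a list. Gaps in the running numbers of the peaks show that some called peaks had been removed before deposit; what was removed is not stated. Contig names of alternate loci in the files are those of GRCh38, so GRCh38 was taken as the build by inference, and peak coordinates are given in it, counted from 1.

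Peaks on chromosomes 1 to 22 and X were analysed. The deposited lists held between 26417 and 417057 peaks and covered between 22.1 and 351 Mb. The read depth of the libraries is unknown, so no interval for counting error on a peak height is given. A fold can still be read as a whole number of fragments: in 10 of 10 lists every fold was a whole multiple of 1 step, with a largest distance of 0.000584 of a step, and every fold had 1 p-value. On that reading the lowest summits held between 10 and 24 fragments, over a background of between 3.31 and 14.3 fragments that was the same for all peaks of a list. The 2 HDGF lists, with the lowest backgrounds, had the highest minimum folds, 2.37 and 2.56. Since the backgrounds differ, folds were compared between lists by rank only.

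Reproducible regions of a protein were made by merging the peaks of its 2 lists where they overlapped by 1 bp or more and keeping the merged regions that held a peak of each list. Overlap between proteins was the share of regions of the shorter set that overlapped a region of the other by 1 bp or more. It was set against 1000 circular shifts of the shorter set along each whole chromosome, with a one-sided permutation p and Benjamini-Hochberg adjustment over the 10 protein pairs; the smallest p these permutations can give is 0.001, or 0.005 where 200 shifts were drawn. A shift along the whole chromosome removes the shared placement of peaks in broad domains as well as shared sites, so shifts by 10 to 100 kb either way were set beside them by plan. Similarity of libraries was the Jaccard index in bp of the 10000 peaks with the highest -log10 p in each list. It was compared within and between proteins by an exact one-sided permutation test over all ways of dividing the 10 libraries into pairs.

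A 1-Mb bin was called dense where its peak count, relative to the mean bin of the list, had a median over the 10 lists above 2. These bins, and every analysis restricted to peaks or genes outside them, were chosen after seeing the data. The gene table used was NCBI RefSeq for GRCh38, with 59098 genes on these chromosomes, among them 19974 protein-coding genes. It gives no strand, so a window of 1 kb around either end of a gene was used in place of the planned window around transcription start sites. Such gene ends include 3' ends. The planned search for the ZEB1 recognition sequence needed a genome sequence and was not run.

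A gene counted as occupied where a reproducible region overlapped the window at either end. Co-occupancy of INTS13 and each partner was tested over protein-coding genes with a Mantel-Haenszel odds ratio stratified by the 8 patterns of the other 3 proteins, with a Mantel-Haenszel chi-square test over genes. For ZEB1 and ZNF609 that odds ratio was infinite, and the stratified difference in percentage points was added after seeing this. Gene lists fixed before the data were examined were compared with all other protein-coding genes, or with all other genes for the small nuclear RNA list, by two-sided Fisher's exact tests. Adjustment was over all 85 tests of 17 lists and 5 proteins, and also over each list alone. The lists were small nuclear and other small RNA genes, replication-dependent histone genes, Integrator subunits, immediate early genes, heat shock and chaperone genes, cytosolic ribosomal protein genes, epithelial genes repressed by ZEB1, cohesin and cohesin loader genes, factors of RNA polymerase II pausing and elongation, p53 targets, cholesterol synthesis genes, DNA replication and E2F targets, monocyte and macrophage genes, liver and erythroid genes, muscle and keratinocyte genes, olfactory receptors and neuronal genes. Peaks, regions and genes are not replicates, so tests over them describe these lists of peaks and not a population of cultures. Neighbouring genes can share a region and are not independent, so p-values over genes may be too small, above all for histone and olfactory receptor genes.

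Named genes were chosen by a rule set before the data were examined. Per protein, the rule takes the 10 protein-coding genes whose best peak at a gene end had the smallest worst rank by fold over the 2 lists. Per INTS13 pair, it takes the 10 genes occupied in all 4 lists with the smallest mean percentile rank. Genes whose ends lie within 1 kb of each other count once, and both are named. Members of lists of 20 or fewer genes may also be named. Other genes are named as chosen after their values were seen, and genes of multicopy families are called uncertain. Some members of the lists are not reported by name here.

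Other settings chosen before the data were examined were a -log10 q of 5 or more, the top 10000 peaks, a reciprocal overlap of 50%, summits within 250 bp, gene windows of 500 bp and 5 kb, other backgrounds, other list lengths, same-numbered libraries and leaving out each library in turn. When a library was left out, the other list stood for the protein. The overlap tests were tested on simulated lists. For independent lists placed in shared blocks, with 9774 regions, overlap was 3.01 times that of shifts along the whole chromosome and 0.978 times that of local shifts. With 30% of sites planted as shared in such blocks, with 9663 regions, overlap lay 23.3 percentage points above local shifts. Simulated intervals were placed at random within blocks, with no smaller clusters. After local shifts 22.1% and 21.9% of simulated regions overlapped, beside 68.5% to 82.3% for the INTS13 pairs. The simulations therefore do not show how local shifts act on lists with broad, clustered or crowded peaks. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.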

Results

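The data are lists of peaks for INTS13, INTS11, HDGF, ZEB1 and ZNF609 in HEK293T cells, with 2 libraries per protein. INTS13 and INTS11 are subunits of Integrator, the complex that cleaves nascent RNA of RNA polymerase II; INTS11 is its endonuclease. HDGF is a chromatin-associated growth factor, ZEB1 is a zinc finger repressor of epithelial genes, and ZNF609 is a zinc finger protein. The study asked whether INTS13 and its interactors occupy the same places in the genome. INTS13 had the longest lists, with 379519 ± 53087 peaks (SD, n = 2), followed by INTS11 with 150763 ± 63054, HDGF with 131269 ± 23289, ZEB1 with 48825 ± 4987 and ZNF609 with 36310 ± 13991. Median peak widths of the 10 lists lay between 402 and 655 bp, and the widest peaks reached between 70.1 and 213 kb.

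Peaks of all 5 proteins were crowded into broad stretches of the genome that were largely shared. These stretches were called by the median of the lists, and not all of them were dense in HDGF. Of the 3043 bins of 1 Mb, 382 (12.6%) were dense in peaks, among them 106 on chromosome 1, 33 on chromosome 13 and 32 on chromosome X, and 0 on chromosomes 4 and 20. These bins held 33.3% ± 1.16 (SD, n = 2) of INTS13 peaks, 55.1% ± 1.89 of HDGF peaks, 65.5% ± 13.3 of INTS11 peaks, 85.0% ± 0.353 of ZEB1 peaks and 88.8% ± 3.67 of ZNF609 peaks. Chromosome 13 carried 3.73% ± 0.104 of INTS13 peaks but 20.5% ± 2.68 of ZEB1 peaks and 28.0% ± 8.23 of ZNF609 peaks, and its dense bins lay between 62 and 95 Mb. Chromosome X carried 1.33% ± 0.0768 of HDGF peaks and between 5.43% and 8.47%, as means, of those of the other proteins. Peak counts per bin correlated within proteins with a median Spearman rho of 0.956 over 5 library pairs, and between proteins with a median of 0.839 over 40 pairs; bins are not independent replicates.

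**Figure D1:**
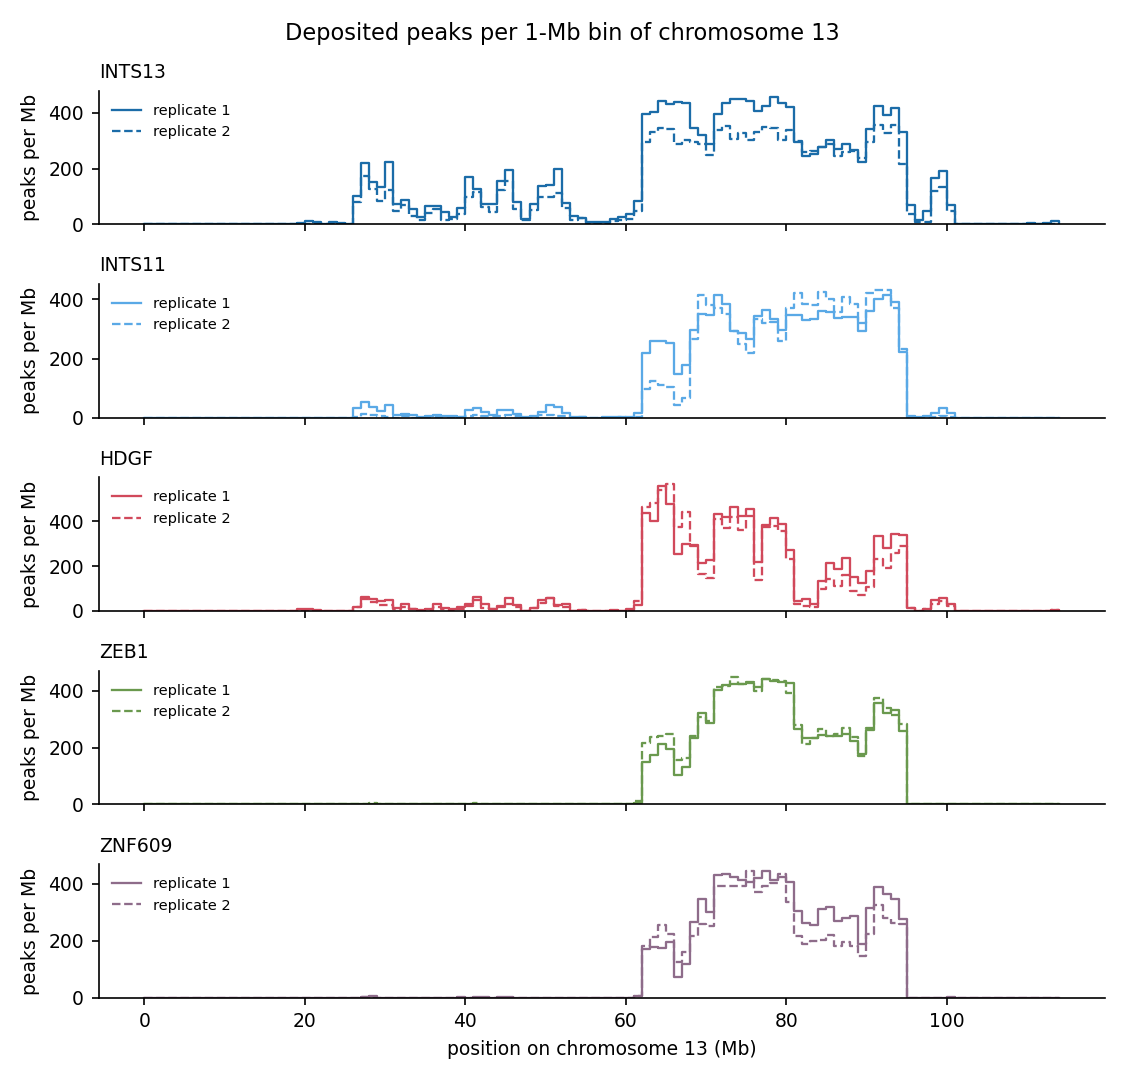
Peaks per 1-Mb bin (y axis) along chromosome 13 (x axis, Mb), with a panel per protein and a line per replicate. Dense bins, called by the median of the lists, lie between 62 and 95 Mb. All 5 proteins have many peaks in this stretch, though HDGF has few in some of its bins. The share of peaks on this chromosome is smallest in INTS13 (3.73%) and largest in ZNF609 (28.0%).

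On average, libraries of the same antibody resembled each other more than libraries of different antibodies. The Jaccard index of the top 10000 peaks was 0.359 ± 0.0467 (SD, n = 5 library pairs) within proteins and 0.231 ± 0.0790 (n = 40) between them. The difference of 0.128 had an exact permutation p of 0.00106, the smallest that all pairings of the libraries can give. Single pairs did not all follow the average. INTS13 replicate 2 and INTS11 replicate 1 had an index of 0.402, above that of the INTS13 replicates, and the HDGF replicates, at 0.290, lay below several pairs of different proteins. The 4 cross pairs of ZEB1 and ZNF609 had a mean index of 0.350, with a range of 0.347 to 0.353, beside 0.352 for the ZEB1 replicates and 0.351 for the ZNF609 replicates. INTS13 was closest to INTS11, with a mean index of 0.316 over 4 library pairs, beside 0.180 with ZEB1, 0.15 with HDGF and 0.147 with ZNF609. INTS13 replicates had an index of 0.387 and INTS11 replicates of 0.415. Among peaks outside dense bins the difference within against between proteins was 0.0499, with the same exact permutation p of 0.00106. With the share of overlapping peaks in place of the index it was 0.0529, with an exact permutation p of 0.0402.

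**Figure D2:**
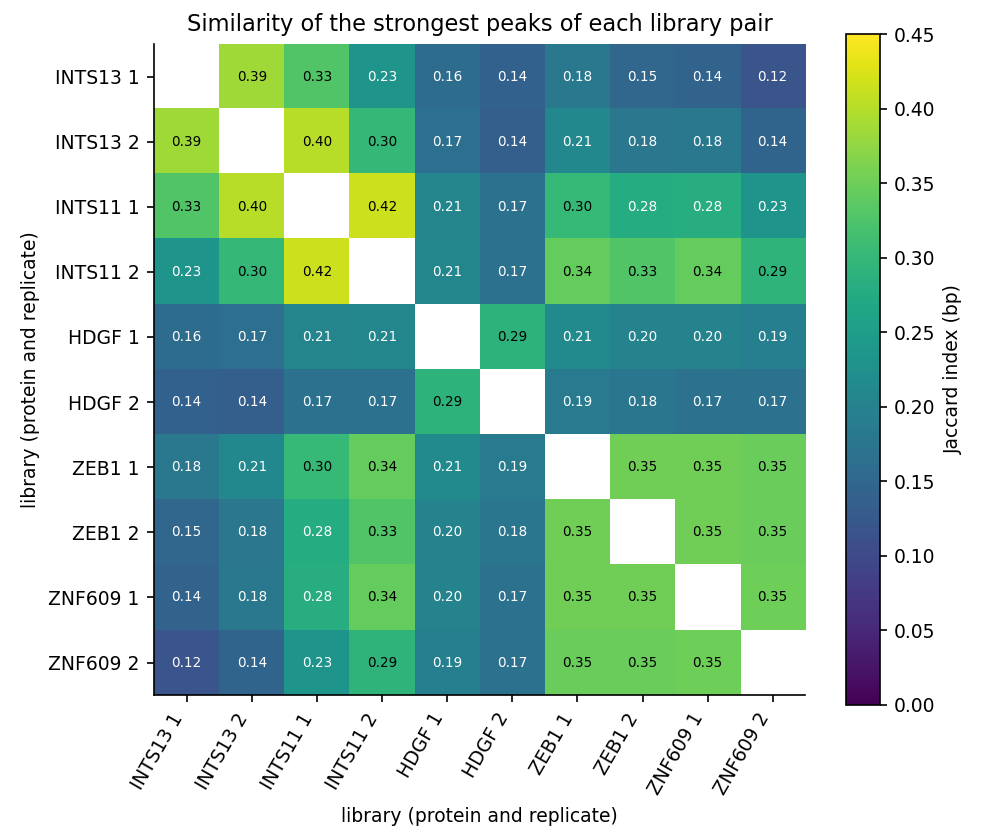
Jaccard index in bp of the top 10000 peaks for each pair of the 10 libraries, which stand in the same order on both axes; colour and printed values give the index. Pairs within a protein average 0.359, pairs between proteins 0.231, and the ZEB1 and ZNF609 cross pairs sit at 0.347 to 0.353.

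Most regions of each partner overlapped an INTS13 region. Reproducible regions numbered 203599 for INTS13, 52921 for INTS11, 44211 for HDGF, 14984 for ZEB1 and 9918 for ZNF609. An INTS13 region overlapped 84.7% of INTS11 regions, 76.6% of HDGF regions, 90.7% of ZEB1 regions and 86.4% of ZNF609 regions. Shifts along whole chromosomes gave 28.9%, 25.3%, 29.8% and 28.9%, so that the log2 ratios were 1.55, 1.6, 1.6 and 1.58, each with an adjusted permutation p of 0.001, the smallest these permutations can give. Between single libraries the shares were 72.4% ± 1.35 (SD, n = 4 library pairs) for INTS11, 62.5% ± 2.22 for HDGF, 77.6% ± 3.28 for ZEB1 and 72.8% ± 1.93 for ZNF609. Differences between partners were not tested; a two-sided exact permutation test of 2 against 2 libraries cannot go below 0.333.

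Much of that overlap was also present after regions were moved by 10 to 100 kb. Local shifts gave 72.0% for INTS11, 68.5% for HDGF, 82.3% for ZEB1 and 81.5% for ZNF609, which leaves log2 ratios of 0.23, 0.16, 0.14 and 0.085, all with an adjusted permutation p of 0.001. Outside dense bins the INTS13 overlap over local shifts was larger on the log2 scale: 0.87 for INTS11 (73.2% of 7290 regions), 0.45 for HDGF (55.4% of 13635), 1.02 for ZEB1 (81.7% of 350) and 0.95 for ZNF609 (76.2% of 143). Local shifts outside dense bins were free to end in a dense bin, where regions had been removed. For any protein pair this lowers the shifted share and raises the ratio, by an amount that was not measured. Replicates of a protein showed the same contrast of whole-chromosome and local shifts. The overlap of the 2 ZEB1 lists was 4.89 times that of whole-chromosome shifts and 1.15 times that of local shifts, and the overlap of the 2 INTS13 lists was 2.68 and 1.39 times.

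**Figure D3:**
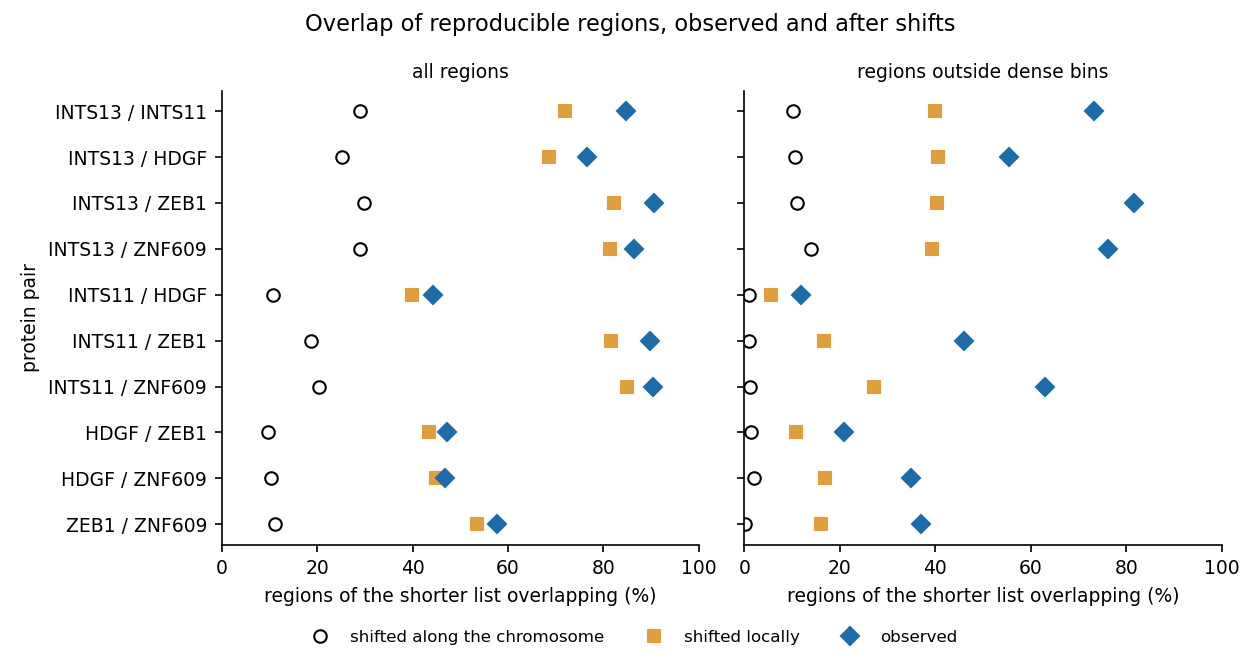
Percent of the regions of the shorter list that overlap the other list (x axis) for each protein pair (y axis), over all regions and outside dense bins; diamonds are observed values, circles the mean of shifts along the whole chromosome and squares that of local shifts. For INTS13 and INTS11 the values over all regions are 84.7%, 28.9% and 72.0%.

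Pairs without INTS13 overlapped as well. Whole-chromosome shifts gave log2 ratios from 2.03, for INTS11 and HDGF, to 2.36, for ZEB1 and ZNF609. Local shifts gave 0.061, for HDGF and ZNF609, to 0.16, for INTS11 and HDGF, and outside dense bins 0.96, for HDGF and ZEB1, to 1.47, for INTS11 and ZEB1. INTS11 regions overlapped 89.6% of ZEB1 regions and 90.5% of ZNF609 regions. Ratios of INTS13 pairs and of other pairs cannot be ranked against each other, since the long INTS13 set caps the ratio.

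INTS13 regions that also carried INTS11 were richer in the other 3 proteins. INTS11 overlapped 42905 of the 203599 INTS13 regions (21.1%). HDGF was at 34.3% of INTS13 regions with INTS11 and 7.46% of those without, a risk ratio of 4.60 (95% interval 4.50 to 4.70). ZEB1 was at 26.7% and 0.480%, a risk ratio of 55.6 (51.7 to 59.7), and ZNF609 at 20.0% and 0.218%, a risk ratio of 92.0 (82.7 to 102.3). These intervals count regions as independent and do not give the spread between libraries, which was wider. No shifted regions were set beside these shares. How far the width and local crowding of the regions set them was therefore not measured. The share with INTS11 was 4.44% outside dense bins and 45.5% inside them, where the risk ratios were 3.91 and 2.69 for HDGF, 41.4 and 20.5 for ZEB1, and 156 and 30.6 for ZNF609. The share was 48.4% without INTS11 replicate 2 and 66.0% for the top 10000 peaks. The risk ratio for HDGF was 2.84 without HDGF replicate 1 and 2.58 without replicate 2, that for ZEB1 12.1 without ZEB1 replicate 1 and 9.19 without replicate 2, and that for ZNF609 22.7 without ZNF609 replicate 1, 13.2 without replicate 2 and 59.6 without INTS11 replicate 2. The top 10000 peaks gave 2.68 for HDGF, 9.30 for ZEB1 and 13.1 for ZNF609, and a -log10 q of 5 or more gave 7.96, 250 and 375.

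Regions of HDGF, INTS13, INTS11 and ZEB1 lay at gene ends more often than shifted regions. Gene ends of protein-coding and long non-coding RNA genes held 16.8% of HDGF regions against 7.49% of shifted ones (log2 ratio 1.17), 14.2% of INTS13 regions (0.80), 13.1% of INTS11 regions (0.71) and 11.2% of ZEB1 regions (0.62), each with an adjusted permutation p of 0.00125. ZNF609 had 8.69% against 7.07%, a log2 ratio of 0.30 with an adjusted permutation p of 0.0689. Local shifts gave log2 ratios of 0.44 for HDGF, 0.25 for INTS13, 0.27 for INTS11, 0.23 for ZEB1 and 0.028 for ZNF609. The differences between proteins were not tested, and their order changed with the setting: over local shifts outside dense bins the ratio was 0.72 for INTS11, 0.63 for HDGF, 0.39 for INTS13 and 0.050 for ZEB1 (350 regions, adjusted permutation p of 0.527), and that of ZNF609 was -0.25. At a -log10 q of 5 or more the ZEB1 ratio was 0.37 with an adjusted permutation p of 0.311. Without ZNF609 replicate 2 the ZNF609 ratio was 0.31 with an unadjusted permutation p of 0.00995.

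INTS13 occupied the ends of most protein-coding genes and the other proteins those of fewer. No share of genes was computed for shifted regions. How far the number and width of the regions set these shares was therefore not measured. The 203599 INTS13 regions lay at ends of protein-coding and long non-coding RNA genes with a log2 ratio of 0.25 over local shifts. With regions found in both replicates, of 19974 genes INTS13 was at 12730 (63.7%), HDGF at 4427 (22.2%), INTS11 at 3485 (17.4%), ZEB1 at 756 (3.78%) and ZNF609 at 313 (1.57%). The shares of single lists were larger, and INTS11 varied most: replicates 1 and 2 gave 79.5% and 68.1% for INTS13, 50% and 22.2% for INTS11, 38.5% and 34.6% for HDGF, 13.3% and 8.48% for ZEB1, and 7.0% and 3.43% for ZNF609. The order of HDGF and INTS11 therefore depends on the list. Outside dense bins the shares of 15367 genes were 54.3%, 12.4%, 5.82%, 0.169% and 0.0390%. INTS13 was at 99.1% of genes with INTS11 and 56.2% of genes without it; the stratified odds ratio was 42.9 (95% interval 29.9 to 61.7). For HDGF the shares were 96.4% and 54.4%, with an odds ratio of 13.6 (11.5 to 16.0). INTS13 was also at 756 of 756 genes with ZEB1 and 313 of 313 with ZNF609. All but 26 and 6 of these belong to the 4607 genes in dense bins, of which 95.3% had INTS13 in any case. Within the patterns of the other 3 proteins, the stratified difference was 2.75 percentage points for ZEB1, with a Mantel-Haenszel chi-square adjusted p of 8.85e-06, and 0.95 points for ZNF609, with p = 0.0685. The differences depended on single libraries: the ZEB1 value was 11.1 points without ZEB1 replicate 1, 15.9 without ZEB1 replicate 2 and 1.16 without INTS13 replicate 2, and the ZNF609 value was 6.09 points without ZNF609 replicate 1, 9.30 without ZNF609 replicate 2 and -0.0243 without INTS13 replicate 2. The differences for INTS11 and HDGF, 28.9 and 31.2 points, were 15.9 and 20.0 without INTS13 replicate 2, and 51 and 16.7 without INTS11 replicate 2. At a -log10 q of 5 or more the ZEB1 and ZNF609 values were 0.20 and -6.11 points, and neither passed; with no strata the ZNF609 value was 36.8 points.

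HDGF lay at ribosomal protein, DNA replication and cholesterol synthesis genes more often than at other genes. It was at the ends of 54 of 83 cytosolic ribosomal protein genes (65.1%), against 22.0% of other protein-coding genes, with a Fisher's exact adjusted p of 1.3e-15. It was at 14 of 24 DNA replication and E2F target genes (58.3%, exact adjusted p = 0.0019) and at 9 of 17 cholesterol synthesis genes (52.9%, adjusted p = 0.0387), among them PMVK, FDPS, MVK and CYP51A1. HDGF was rarer at replication-dependent histone genes, with 4 of 69 (5.8%, exact adjusted p = 0.00412), and at olfactory receptor genes, with 1 of 390 (adjusted p = 9.24e-40). It was at 11 of 23 immediate early genes and 9 of 18 p53 targets, including CDKN1A, BAX and GADD45A, each with an exact adjusted p of 0.0505, and at 0 of 19 neuronal genes (adjusted p = 0.0604). Outside dense bins HDGF was at 33 of 59 ribosomal protein genes, 55.9% against 12.2% (exact adjusted p = 3.86e-14), and at 9 of 19 E2F targets (adjusted p = 0.00274). The E2F targets did not pass with windows of 500 bp (33.3% against 16%, exact adjusted p = 0.245), against genes occupied by another protein (63.2% against 33.5%, adjusted p = 0.171) or at a -log10 q of 5 or more (16.7% against 2.64%, adjusted p = 0.0584). The cholesterol genes did not pass outside dense bins (3 of 11, 27.3% against 12.4%, exact adjusted p = 0.687) nor without HDGF replicate 1 (58.8% against 34.6%, adjusted p = 0.181). The histone genes did not pass outside dense bins (2 of 67, 2.99% against 12.4%, exact adjusted p = 0.102) nor without HDGF replicate 2 (26.1% against 38.5%, adjusted p = 0.158). At a -log10 q of 5 or more HDGF was at 2 of 69 histone genes against 2.66% of other genes, too few to give a direction.

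INTS13 was at 55 of 69 replication-dependent histone genes (79.7% against 63.7%, exact adjusted p = 0.0387), whose transcripts are cleaved without polyadenylation, and at 66 of 83 ribosomal protein genes (79.5%, adjusted p = 0.0255). It was rarer at liver and erythroid genes, with 6 of 19 (exact adjusted p = 0.0436), where ALB, HBB and the fibrinogen genes FGA, FGB and FGG had no region, and at olfactory receptor genes, with 37 of 390 (adjusted p = 1.1e-111). Without INTS13 replicate 1 the differences at histone and ribosomal protein genes were 13.1 and 12.6 points and did not pass (exact adjusted p = 0.104 and 0.0733). Without INTS13 replicate 2 that at liver and erythroid genes was -26.9 points (exact adjusted p = 0.0505). Outside dense bins INTS13 was at 53 of 67 histone genes (exact adjusted p = 0.000597). There the differences at ribosomal protein genes (42 of 59, 71.2% against 54.2%) and at liver and erythroid genes (4 of 17, 23.5% against 54.3%) were 17.0 and -30.8 points, beside 15.9 and -32.2 over all genes. With fewer genes they did not pass (exact adjusted p = 0.0745 and 0.102). At a -log10 q of 5 or more INTS13 was at 5 of 69 histone genes, -10.9 points from the background (exact adjusted p = 0.215), and for the top 10000 peaks at 2 of 69, too few to give a direction. Among genes occupied by another protein, 96.9% of the background had INTS13, which leaves no room for a difference at ribosomal protein genes (54 of 56), and only 2 liver and erythroid genes were left. Histone and globin genes have close copies, which makes single members uncertain. Neighbouring histone, olfactory receptor, globin or fibrinogen genes can also share a region or lack one together. Fisher's exact test counts each gene as independent. The p-values of these lists may therefore be too small. At genes of small nuclear and other small RNAs, a list that mixes genes of RNA polymerase II and III, INTS13 was at 18 of 28 (64.3% against 45.6%, exact adjusted p = 0.243) and INTS11 at 5 of 28 (adjusted p = 0.774). INTS11 replicate 1 alone was at 16 of 28 (57.1%, exact adjusted p = 0.0719) and replicate 2 at 5 of 28. Several genes of this list also have close copies, and most members without an INTS13 region are of that kind, so their lack of a region is uncertain. Whether copies lowered these shares was not tested. By annotated class, INTS13 was at 29.9% of 154 small nuclear RNA genes and 63.7% of protein-coding genes. INTS11 was at 28 of 83 ribosomal protein genes (33.7% against 17.4%, exact adjusted p = 0.00412; outside dense bins 9 of 59, 15.3% against 5.78%, adjusted p = 0.0632) and at 7 of 390 olfactory receptor genes (adjusted p = 4.94e-22).

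ZEB1 was at 4 of 17 cholesterol synthesis genes, among them PMVK, FDPS and LSS (23.5% against 3.77%, exact adjusted p = 0.0278), and at 0 of 390 olfactory receptor genes (adjusted p = 9.42e-06). All 4 cholesterol genes lie in dense bins, and the call was not kept without ZEB1 replicate 1 (23.5% against 8.47%, exact adjusted p = 0.225) or without ZEB1 replicate 2 (29.4% against 13.3%, adjusted p = 0.262). With these 4 genes left out, the genes outside dense bins say nothing on the call. At a -log10 q of 5 or more and for the top 10000 peaks ZEB1 was at 0 of the 17 genes, against 0.225% and 0.927% of other genes, too few to give a direction. ZEB1 regions found in both replicates were at 0 of 25 epithelial genes that it is known to repress, against 3.79% of other genes (Fisher's exact adjusted p = 1). The single lists differed: ZEB1 replicate 1 was at 7 of the 25 (28.0%, beside 13.3% of all protein-coding genes) and replicate 2 at 1 (4.0%, beside 8.48%). INTS13 was at 22 of those 25 (88.0%, exact adjusted p = 0.0599). No list passed for ZNF609 by Fisher's exact tests, with 1 call when adjusted over the list alone.

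In all, 13 of the 85 tests passed, 7 above and 6 below the background; 16 passed when adjusted over the list alone. Against genes occupied by at least 1 other protein, 3 calls were left, HDGF at ribosomal protein genes above the background and 2 below it. Of the 13 calls, 9 were kept with windows of 500 bp, 4 at a -log10 q of 5 or more and 5 for the top 10000 peaks. HDGF at ribosomal protein and at olfactory receptor genes passed under every setting run, and the other 11 did not. The remaining lists gave no call for any of the 5 proteins. For them INTS13 and HDGF occupied 10 and 4 of 15 Integrator subunit genes, 13 and 6 of 15 heat shock and chaperone genes, 11 and 3 of 14 cohesin genes, 15 and 6 of 21 pausing and elongation factor genes, 12 and 1 of 16 monocyte and macrophage genes, and 7 and 1 of 15 muscle and keratinocyte genes.

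**Figure D4:**
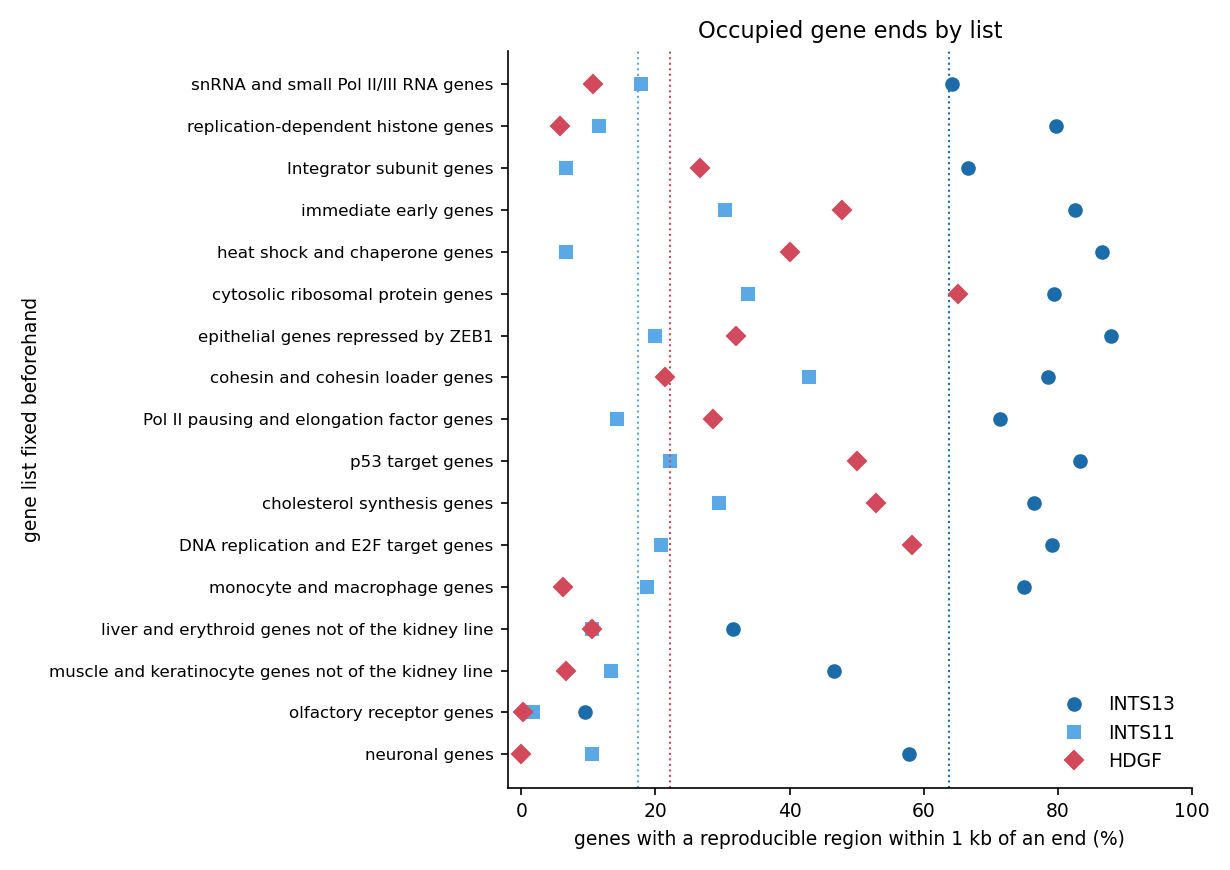
Percent of the genes of each list with a reproducible region at a gene end (x axis) for INTS13, INTS11 and HDGF, by list (y axis); dotted lines give the share of all protein-coding genes for each protein. HDGF stands at 65.1% of ribosomal protein genes beside 22.2% of all protein-coding genes.

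A small set of genes carried some of the strongest gene-end peaks of every antibody, beside genes named for 1 protein only. NBPF1, TLE4 and PCDH9 were among the top 10 genes of all 5 proteins. TLE4 encodes a corepressor of the Groucho family and PCDH9 a protocadherin; NBPF1 belongs to a multicopy family, so its signal is uncertain. Near TLE4 the INTS13 replicate 1 peak ran from 79562597 to 79575259 on chromosome 9, with the authors' fold at 9.69 in that list and 7.12 in replicate 2. Near PCDH9 it ran from 67224950 to 67231972 on chromosome 13, with folds of 8.05 and 5.49, and near NBPF1 from 16604618 to 16619220 on chromosome 1, with folds of 8.66 and 7.12. In HDGF the folds were 8.28 and 7.90 at TLE4, 7.89 and 8.36 at PCDH9, and 8.48 and 8.59 at NBPF1. The strongest HDGF peak near TLE4 ran from 79679362 to 79736487 in replicate 1, apart from that of INTS13. Other lists held broader peaks there. In replicate 1 the ZEB1 peak ran from 79572789 to 79743240 (170 kb) and the ZNF609 peak from 79571944 to 79743283 (171 kb). Both overlapped the INTS13 peak and spanned the HDGF peak. The INTS11 replicate 1 peak was 77.4 kb wide. The peaks near TLE4 therefore need not be separate sites. CSNK1E, a casein kinase, which shares ends with the readthrough gene TPTEP2-CSNK1E, was among the top 10 of INTS13, INTS11 and HDGF, and GPRIN2 of INTS13, INTS11 and ZNF609. Genes in the top 10 of HDGF and of no other protein included IRF2BP2, a transcriptional corepressor, with folds of 7.89 and 8.36. ARF1, a small GTPase of the Golgi, with 6.31 and 6.74, and EPHX1, an epoxide hydrolase, were others. This rests on the cut at 10 genes and does not make them specific to HDGF. ARF1 and EPHX1 also had INTS13 peaks in both lists and were among the top 10 of the INTS13 and HDGF pair. The HDGF replicate 1 peak named for ARF1 was also that of C1orf35, so distinct genes need not be distinct peaks. In all, the 5 lists named 24 distinct genes, of which 21 lie in dense bins and 11 were named for 1 protein only. The INTS13 pairs put TLE4, NBPF1 and PCDH9 in their first 3 places for all 4 partners.

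Peak heights in shared regions rose and fell together to a moderate degree. Between replicates the Spearman rho of the folds across regions lay between 0.299, for ZNF609, and 0.440, for INTS11. INTS13 heights followed INTS11 heights with a rho of 0.415 over 44819 regions, HDGF with 0.298, ZEB1 with 0.281 and ZNF609 with 0.181. The highest value between proteins was 0.456, for INTS11 and ZEB1, and the lowest 0.127, for HDGF and ZNF609. Regions are not independent replicates, and no p is given.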

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

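No test was run for this part. Peaks on alternate contigs of the assembly were in none of the comparisons, and every list held some, above the 3 counts that a count of 0 allows. HDGF had 22 in replicate 1 and 12 in replicate 2, INTS11 46 and 33, INTS13 93 and 68, ZEB1 15 and 8, and ZNF609 16 and 8. They stand out only because no comparison used them.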

How the results depend on the processing

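The local shifts with a second filter and everything outside or inside dense bins were chosen after seeing the data. The similarity of libraries kept its direction and its side of the threshold under every alternative run. So did the overlap of all 10 pairs above whole-chromosome shifts. The similarity fell to 0.0529 (exact permutation p = 0.0402) with the share of peaks in place of bp. Same-numbered libraries, compared as a replicate block, gave log2 ratios of 1.45 (INTS13 with ZNF609) to 2.17 (ZEB1 with ZNF609). For the same protein pairs different-numbered libraries gave 1.48 and 2.17. The widest gap was 2.05 for same-numbered against 1.98 for different-numbered libraries, for INTS11 with ZEB1, and the sign of the gap varied between pairs. Ratios over whole-chromosome shifts also hold the shared broad placement of peaks, so these values do not exclude a replicate block. With local shifts, HDGF with ZEB1 gave log2 ratios of 0.046 at a -log10 q of 5 or more and 0.047 for the top 10000 peaks, and HDGF with ZNF609 0.0060 and 0.032, none past the threshold. The gene-end ratio of ZEB1 was 0.37 at a -log10 q of 5 or more and 0.050 over local shifts outside dense bins; that of ZNF609 was -0.25 in the latter and 0.18 to 0.31 with a library left out. Co-occupancy with INTS13 was 0.20 points for ZEB1 at a -log10 q of 5 or more; for ZNF609 it was 36.8 points with no strata, -6.11 at a -log10 q of 5 or more, and -0.0243 to 9.30 with a library left out. The INTS13 share with INTS11 was 66.0% for the top 10000 peaks, 4.44% outside and 45.5% inside dense bins, and 14.6% to 48.4% with a library left out. List calls above the background numbered 12 with 5 kb windows, 1 against genes occupied by another protein, 1 at a -log10 q of 5 or more, 2 for the top 10000 peaks, and 5 to 9 with a library left out; calls below numbered 2 against occupied genes, 3 at a -log10 q of 5 or more, 3 for the top 10000 peaks, 3 outside dense bins and 5 to 7 with a library left out. At a -log10 q of 5 or more, INTS13 at histone genes turned to -10.9 points. Other changes of sign rest on too few genes or on a saturated background and measure no turn: ZEB1 at 0 cholesterol genes (-0.225 points at a -log10 q of 5 or more, -0.927 for the top 10000 peaks, -0.169 outside dense bins, where no occupied member was left), HDGF (0.241) and INTS13 (-1.90, top 10000 peaks) at 2 histone genes each, and INTS13 against occupied genes at ribosomal protein (-0.428) and liver and erythroid genes (3.15). Without the highest 1% of folds the replicate rho was 0.415 for INTS13, 0.419 for INTS11, 0.315 for HDGF, 0.285 for ZEB1 and 0.269 for ZNF609; it was 0.276 for INTS13 with HDGF, 0.211 for INTS11 with HDGF, 0.432 for INTS11 with ZEB1, 0.126 for HDGF with ZEB1, 0.101 for HDGF with ZNF609 and 0.388 for ZEB1 with ZNF609. Stricter lists hold fewer regions, which costs calls by construction; the cause was not tested for the other changes. The ZEB1 recognition sequence was not run, for want of a genome sequence. Read depth is unknown, and what it limits was not measured.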

Other observations

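Of the tests in this part, those on a uniform background, copy number, the gene ends of chromosome 13, another batch or subline, shared sites, and the density of peaks at INTS13 and HDGF pairs alone were chosen after the result was seen, as was every value outside dense bins. The tests on copy number, another batch and shared sites were also changed after a first version had been seen, because these first versions used the lists that had defined the dense bins, a shared reference, and a ratio capped by the long INTS13 set.

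Outside dense bins, of the 10 genes with the strongest HDGF peaks at their ends only TLE4 was also among the top 10 of another protein. TLE4 led in all 5 lists there, though not with the same peak, and GPRIN2 and STX4, a syntaxin of membrane fusion, were among the top 10 of INTS13, INTS11, ZEB1 and ZNF609. For HDGF the list held the neighbours APRT, an enzyme of adenine salvage, and CDT1, a replication licensing factor, with folds of 5.52 and 5.81, and EIF1, a translation initiation factor, with folds of 4.93 and 5.11. The APRT and CDT1 peak of HDGF replicate 1 ran from 88809135 to 88809981 on chromosome 16. In all, 28 of the 35 genes named there were named for 1 protein only. This too rests on the cut at 10 genes. The neighbours APRT and CDT1, and EIF1, were also among the top 10 of the INTS13 and HDGF pair outside dense bins. HDGF was also at 6 of 14 heat shock and chaperone genes (42.9% against 12.4%, Fisher's exact adjusted p = 0.0471) and 6 of 13 p53 targets (46.2%, adjusted p = 0.0343) outside dense bins.

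Gene classes differed too. Outside dense bins, INTS13 was at the ends of 54.3% of 15367 protein-coding genes, 39.5% of 342 transfer RNA genes and 33.6% of 15264 long non-coding RNA genes. It was at 22.7% of 128 small nuclear RNA genes and 19.3% of 12919 pseudogenes. INTS11 was at 1.56% of these small nuclear RNA genes and 5.82% of protein-coding genes. HDGF was at 10.8% of 942 small nucleolar RNA genes, many of which lie within introns of ribosomal protein and other host genes, beside 12.4% of protein-coding genes and 1.55% of pseudogenes. These shares were not tested against each other. The windows at the ends of a short gene overlap, so less sequence is searched than at a long gene, and the classes differ in length. Many small nuclear RNA genes also have close copies, which makes their shares uncertain.

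The dense bins, called by the median of the 10 lists, invite a technical reading, though not all of them were dense in HDGF. The design names no biological explanation for them, so gene density was tested beside the technical ones. Every fold in 10 of 10 lists was a whole multiple of 1 step with 1 p-value, so that a single background per list, blind to local read density, is a candidate source of the crowding. Copy number of the cell line may add to it, but was not measured. Dense runs were taken from the replicate 1 lists. At 10 of 13 run edges with no rise in gene ends (76.9%), all 5 replicate 2 lists rose into the run. Over all 51 edges 41 did so, so edges with no rise in gene ends did not stand apart. Replicate lists share their broad peak density, and another regional property of chromatin would give the rise as well. The test therefore does not decide on copy number. Gene-rich domains could contribute, since dense bins held 1.88 times the gene ends of other bins (95% range of shifts 0.959 to 1.32). They are argued against for chromosome 13, where dense bins held 0.244 times as many, 2.48 against 10.2 per bin.

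HDGF lists differed from the 8 others in how their peaks spread over dense bins, with few on chromosome X. The base composition of the libraries may be behind this: across dense bins the relative HDGF density rose with gene ends, a stand-in for base composition, with a Spearman rho of 0.584, though a preference of HDGF for genes would give the same sign. Another batch or subline of cells cannot be told apart from the antibody, since the deviations of the 2 HDGF lists correlated with a rho of 0.973 and both share the antibody. HDGF regions did lie at gene ends more often than local shifts, with a log2 ratio of 0.44; whether this accounts for their spread over dense bins was not tested.

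Outside dense bins the overlap of INTS13 with its partners stood above local shifts, some of which could end in dense bins emptied of regions. The overlap also stood above local shifts in the 1737 bins under 0.5 of the mean density. There the median log2 ratio of the 4 INTS13 pairs was 2.37. It was 2.02 for INTS11 (647 regions), 2.72 for ZEB1 (38), 3.14 for ZNF609 (27) and 0.89 for HDGF (2300). For INTS11, 56.1% of regions overlapped there, against 13.9% after local shifts. For HDGF the excess over local shifts was 11.2 percentage points, beside 14.8 over all bins outside the dense ones. Whether leftover differences in peak density between 1-Mb bins add to the overlap stays open. The ratio rises as the shifted share falls, a local shift could leave these bins, and ZEB1 and ZNF609 had few regions. Sites that attract peaks in every library cannot be told apart from sites of INTS13 pairs: the median log2 odds ratio of the INTS13 pairs lay 0.65 above that of the 6 other pairs, whereas on the ratio scale the difference was -0.24. Whether such sites are open chromatin or sites of Integrator stays open, and may be asked with the input libraries, not used here.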
